A study of Homo sapiens with 2 samples.

How the data were processed

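Two-colour Agilent whole human genome arrays (design 014850, per the file headers) were used for 2 samples of 293T cells, 1 transfected with empty pSG5 and 1 with the DOCK10 plasmid. Per the labels, the transfected RNA carried Cy5 and RNA of untransfected cells carried Cy3 on both arrays, with no dye swap. The scanner files were made with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes and the file headers. The deposited log10 ratios of Cy5 over Cy3 follow linear and Lowess dye normalisation within each array, per the series description and the file headers. The deposited files also give the intensity of each spot in both channels before and after background subtraction and dye normalisation, and the authors' software adds an error score for each log10 ratio. A matrix of log2 ratios per probe was deposited as well, and it equalled the scanner ratios within 0.005, with a median of 0 in each column. Direction and scale of that matrix were thereby settled, and no centring beyond that of the scanner files was found in it. The software sets the ratio to 0 where neither channel is significant, which held for 8625 and 8930 spots.

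Each array held 43376 non-control spots of 41000 probes, of which 264 were spotted 10 times. Ratios were taken to log2. Control spots and spots with an outlier flag on either array (122 on the pSG5 array and 172 on the other) were left out, and a spot was used if it was well above background and unsaturated in both channels of both arrays. Spots of a probe were averaged (at least 5 usable spots for a probe spotted 10 times), then probes of a gene. This gave 21514 probes and 12718 genes. For 4381 genes with several probes, the median SD of the difference between probes was 0.11, and for 183 repeated probes the median SD between spots was 0.06. Saturated Cy5 spots numbered 350 on the pSG5 array and 312 on the other. 274 probes were saturated in Cy5 on both arrays, 39 on the pSG5 array alone and 7 on the other alone. Spots and probes do not replace arrays in a comparison between conditions, and with 1 array per group the precision of that comparison is unknown. Each array lay on a slide of its own, so slide and group cannot be told apart.

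The scanner files carry no gene names. The authors' matrix named 32021 probes; 30661 of these names were found in the RefSeq gene table of assembly GRCh38.p14, 1926 of them as an older symbol that was updated. A further 35 probes were named by accession, 121 had a name and an accession that disagreed and were not named singly, and 8944 stayed unnamed. The array design refers to an earlier assembly, so no coordinates from the table were used.

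The main comparison was the difference of the log2 ratios, DOCK10 minus pSG5, in which dye bias and the reference cancel only as far as both arrays read the reference alike. The ratios against the reference were the other comparisons. Differences of at least 2-fold were counted, with no test, since 1 array per group allows none. The Cy3 channel of both arrays, centred on its median, served as a measure of noise between slides, on the assumption that 1 extract of untransfected cells was used on both, which is not given in the sources used here. For genes not well above background in Cy5 of 1 array, a bound was computed after Aquantile normalisation of the processed signals, against the higher of the lowest signal well above background and the gene's own signal. Gene lists, 35 in all and fixed before the data were examined, were ranked by their median among 10000 random lists of equal size, matched in 10 bins of mean log2 signal, where at least 5 genes were measured. This describes these arrays and tests no hypothesis about the conditions.

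The rule for named genes was fixed beforehand too. It took DOCK10, then up to 12 genes per direction that differed by at least 2-fold and at least 2 combined errors with the same direction in Cy5 compared directly, then up to 5 bounds per direction. It also took up to 10 genes per direction beyond 2-fold from the reference on both arrays, and up to 3 members per list, by the difference or by the mean ratio. Genes with a placeholder name were passed over.

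Areas with deviating spots were defined after the data were seen. A spot counted as lying in one if at least 4 other spots within 4 rows and 2 columns had ratios of 2-fold or more in one direction on an array; this held for 1014 of 43376 spots, 938 of them on the array labelled DOCK10 and 76 on the pSG5 array.

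The alternatives were normexp background correction (offset 50) with loess, on median spot signals because the files hold no mean spot signals although the plan named them, background-subtracted signals (floor 1) centred without loess, the authors' matrix, no filter or a stricter filter on dim probes, the brightest probe per gene, median centring, direct comparison of Cy5, a 1.5-fold threshold, an error criterion and 20 signal bins. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, were used. The steps were tested on simulated data for the DOCK10 minus pSG5 comparison over 12718 genes. Of 50 genes changed 3-fold and 50 changed 4-fold, all 50 each passed 2-fold. Of 50 changed 2-fold, 24 passed, and of 50 changed 1.5-fold, 1 passed. No unchanged gene passed. A list of 20 genes shifted by 0.30 reached percentile 100, and 7 of 200 unshifted lists (3.50%) fell outside the range. The simulated noise was the SD between probes, 0.11, and leaves out noise between slides. It was the same for every spot whatever its signal, and the measured differences had an SD of 0.23. The simulation is thus no guide to false calls among dim genes.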

Results

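Gene expression was measured in 293T cells, a highly transfectable derivative of the human embryonic kidney line HEK293, after transfection with a plasmid encoding HA-tagged DOCK10 isoform 1 or with the empty pSG5 vector. DOCK10 is a guanine nucleotide exchange factor of the DOCK family. RNA was collected 24 h after transfection. Each of the 2 samples was labelled with Cy5 and hybridised with Cy3-labelled RNA of untransfected 293T cells to its own two-colour Agilent whole-genome array, so that each group held 1 array. None of the differences below therefore has a replicate check, and no p-value is given. Of 43376 non-control spots, 61.8% were well above background in Cy5 on the pSG5 array and 60.0% on the array labelled DOCK10. In Cy3 these shares were 58.9% and 55.6%. A measured gene had at least 1 probe that was well above background and unsaturated in both channels of both arrays, which left 12718 genes. Errors after ± are those of the scanner software's error model, combined over both arrays for a difference. They are technical, cover a single array each and had a median of 0.30 on the log2 scale for a difference between the arrays. No coordinates are given, because the array design was built on an older genome assembly than the annotation at hand.

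DOCK10 itself was read first, because its transcript would check the label of the transfected sample. Both DOCK10 probes, A_24_P391811 and A_23_P16722, were not well above background in either channel of either array. Their Cy5 signals were 4.57 and 4.59 on the array labelled DOCK10 and 4.56 and 4.53 on the pSG5 array. In Cy3, the untransfected reference, they were 23.2 and 13.9 on the array labelled DOCK10 and 5.22 and 5.76 on the pSG5 array. The lowest Cy5 signal counted as well above background was 19.3 and 19.0 on these arrays, and the median Cy5 signal of negative control spots was 5.09 and 4.97. DOCK10 mRNA from the plasmid was thus not detectable with these probes, and their place relative to the plasmid's insert was not given in the sources used here. The labels could not be checked in this way, and the sample is called the array labelled DOCK10 throughout.

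The direct question of the design was which transcripts differed between cells given the DOCK10 plasmid and cells given the empty vector. At a difference of 2-fold or more, 26 genes were higher and 11 lower on the array labelled DOCK10, out of 12718. The higher genes included transcripts of the mitochondrial genome and several long nuclear transcripts. ND5 and ND6, subunits of respiratory complex I encoded in mitochondrial DNA, were 2.99-fold and 2.59-fold higher (log2 difference 1.58 ± 0.39 and 1.37 ± 0.41). Each was read by 1 probe, with a mean log2 signal of 6.01 for ND5 and 5.75 for ND6. ANKRD11, a chromatin regulator, was 2.88-fold higher (1.52 ± 0.31), and its 4 probes gave differences of 1.20 to 1.89. GOLGB1, which encodes the Golgi tethering protein giantin, was 2.52-fold higher (1.33 ± 0.30) over 2 probes, and AKAP9, a scaffold of the centrosome and Golgi, was 2.36-fold higher (1.24 ± 0.30).

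The remaining higher genes named by the rule fixed before the data were examined were SCX, the tendon transcription factor scleraxis (1.48 ± 0.34), the kinesin KIF24 (1.39 ± 0.46), ANKRD36B (1.29 ± 0.36), the imprinted antisense RNA KCNQ1OT1 (1.20 ± 0.30), BSN, which encodes the presynaptic protein bassoon (1.17 ± 0.39), the non-coding RNA LINC00999 (1.16 ± 0.30) and the decoy receptor TNFRSF6B (1.13 ± 0.33). ANKRD36B belongs to a family of near-identical copies, so its probes can read related transcripts. Of the 26 higher genes, 25 lay below the untransfected reference on the pSG5 array and all 26 above it on the array labelled DOCK10, sides that selection on the difference favours. GOLGB1 stood at -0.99 on the pSG5 array and 0.34 on the array labelled DOCK10, and ANKRD11 at -0.58 and 0.94. None of the 26 had a spot in an area of a slide with many deviating spots.

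**Figure D1:**
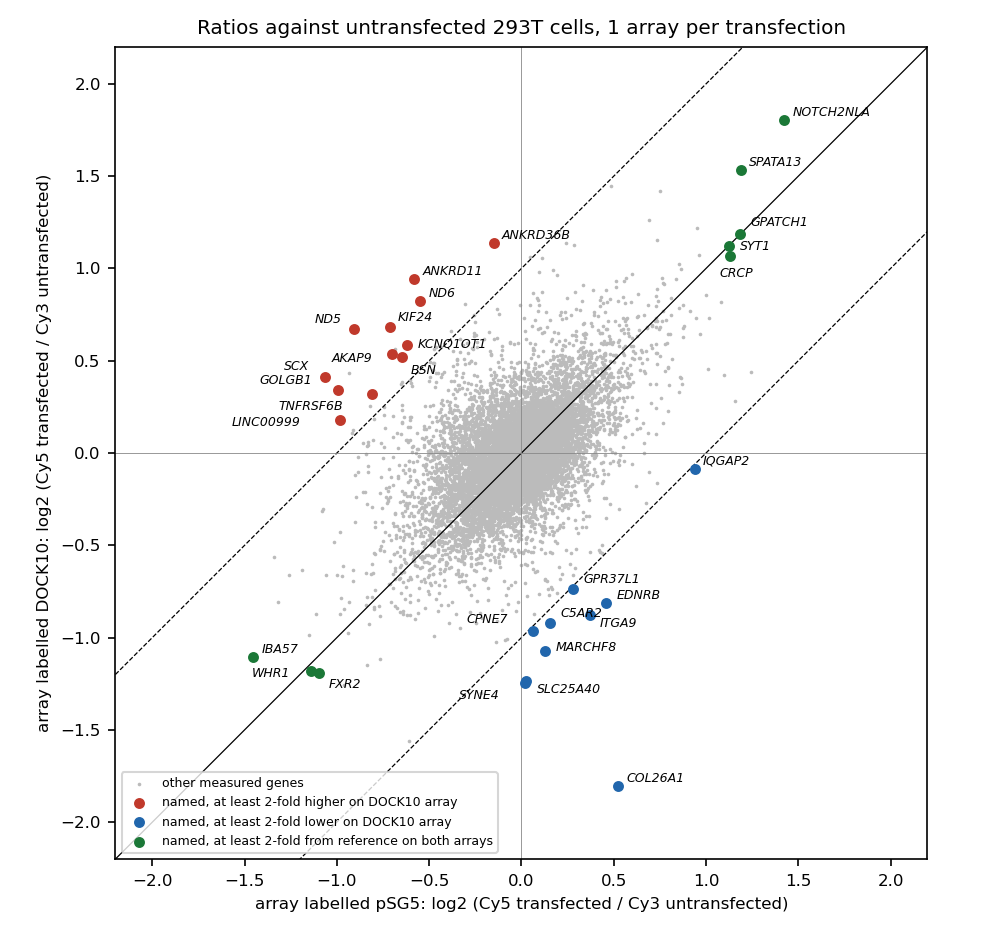
Log2 ratio of transfected over untransfected 293T cells for 12718 measured genes, on the pSG5 array (x axis) and on the array labelled DOCK10 (y axis), 1 array each; the dashed lines mark a 2-fold difference between the arrays. The red genes, such as ND5 at -0.91 and 0.67, lie mostly below the reference on the pSG5 array and above it on the other, and COL26A1 at 0.52 and -1.81 lies farthest on the lower side.

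Among the 11 lower genes, COL26A1, which encodes a collagen, was 5.03-fold lower on the array labelled DOCK10 (log2 difference -2.33 ± 0.48). The endothelin receptor gene EDNRB (-1.27 ± 0.39), the nuclear envelope gene SYNE4 (-1.27 ± 0.34), the integrin gene ITGA9 (-1.25 ± 0.45), the ubiquitin ligase gene MARCHF8 (-1.20 ± 0.49), the complement receptor gene C5AR2 (-1.07 ± 0.42), CPNE7 (-1.03 ± 0.41) and the scaffold gene IQGAP2 (-1.03 ± 0.35) followed. SLC25A40 (-1.26) and GPR37L1 (-1.02) were lower on the mean of 2 probes that disagreed, with SDs between probes of 1.43 and 1.12. The lower genes rested less on the transfected cells than on the reference. For 7 of the 11, the Cy3 signal of the untransfected reference differed more between the arrays than the Cy5 signal did, against 1 of the 26 higher genes. COL26A1 differed by -0.90 in Cy5 and by 1.42 in Cy3. SYNE4 differed by -0.07 in Cy5 and by 1.18 in Cy3, whereas ANKRD11 differed by 1.51 in Cy5 and by -0.03 in Cy3. In addition, 6 of the 11 lower genes had a spot in a deviating area of a slide.

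**Figure D2:**
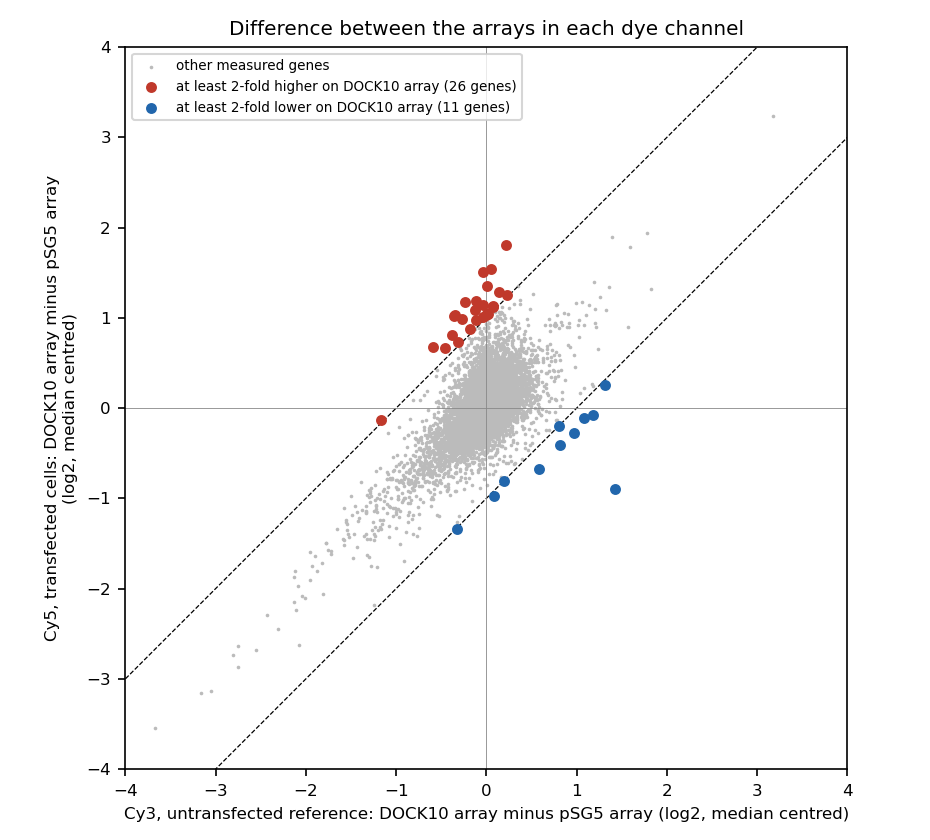
Difference between the arrays (DOCK10 minus pSG5, log2, centred on the median) in Cy3, the untransfected reference (x axis), and in Cy5, the transfected cells (y axis), with 1 point per gene and dashed lines at a 2-fold difference of the ratios. The 26 higher genes centre on a Cy3 difference of -0.08, and the 11 lower genes on 0.82.

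The arrays differed more in single channels than in the ratios. The Cy3 channel, labelled as untransfected reference RNA on both arrays, though not known to be of 1 extract, differed by 2-fold or more for 161 genes, with 29 higher and 132 lower on the array labelled DOCK10, and the Cy5 channel for 186, with 54 higher and 132 lower. Shifts shared by both dyes of a spot cancel in the ratios, and 97.3% of genes differed by less than 1.5-fold in the ratio. The noise of the ratios between slides was not measured. The count depended on the processing, with 5 genes higher and 0 lower after another background correction with an added offset. ANKRD11 (1.31), GOLGB1 (1.22), AKAP9 (1.11) and KCNQ1OT1 (1.07) were then still beyond 2-fold, whereas ND5 stood at 0.63, ND6 at 0.39, KIF24 at 0.42 and COL26A1 at -0.47. A stricter filter on dim probes left 10 of the 26 higher genes measured, all 10 still beyond 2-fold, and 0 of the 11 lower genes, among 7505 genes. This filter leaves the values of the remaining probes as they were. A gene read by 1 probe, as were 19 of the 26, therefore keeps its difference, so the 10 are little check. When Cy5 was compared directly between the arrays, 20 of the 26 higher genes and 1 of the 11 lower genes stayed beyond 2-fold.

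Some genes were well above background in Cy5 on 1 array only, which allows a bound but no ratio. A bound of 2-fold or more was reached by 90 genes higher and 60 genes lower on the array labelled DOCK10. In 57 of the 90 and 52 of the 60, the untransfected reference in Cy3 crossed its background on the same array. The highest bounds were those of TSPAN11 (at least 18.4-fold), LINC00507 (at least 15.6-fold), DMRTB1 (at least 15.6-fold), HGD (at least 8.76-fold) and AQP4-AS1 (at least 5.85-fold). In the untransfected reference, too, TSPAN11, DMRTB1, HGD and AQP4-AS1 were well above background on the array labelled DOCK10 only, and LINC00507 lay in a deviating area. On the lower side stood PRAMEF8 (at least 6.55-fold), SOX11 (at least 4.27-fold), SLC23A3 (at least 3.73-fold), BIRC7 (at least 3.56-fold) and HOXA-AS3 (at least 3.56-fold). Of these, only the apoptosis inhibitor gene BIRC7 was well above background in the reference on both arrays. These bounds compare Cy5 between slides, without the correction that a ratio gives.

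Gene lists fixed before the data were examined were described by the percentile of their median difference among 10000 random lists of matched signal. Of 33 lists with at least 5 measured genes, 6 lay outside the central 95% of random medians, called the range below. For lists drawn at random, 1.65 would lie outside. Genes of a real list may vary together, which random lists leave out, so 1.65 is no measure of chance for these lists. Immediate early genes, the rapid transcriptional targets of growth and stress signals, were higher on the array labelled DOCK10 (median 0.14, percentile 99.9). Of their 26 measured members 20 lay above 0, and 1 passed 1.5-fold. FOS stood highest (0.76 ± 0.42), followed by JUN (0.50 ± 0.30 over 10 spots) and KLF2 (0.49 ± 0.35). Each of these members lay within 2 errors of 0, and a spot of JUN lay in a deviating area of a slide. After the background correction with an added offset, the list stayed outside the range (0.13), but FOS stood at 0.02 and KLF2 at 0.20, with JUN at 0.48.

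Lists of metabolism and replication lay on the lower side, each by a small amount. Cholesterol synthesis genes had a median of -0.10 (percentile 0.82), with 19 of 24 below 0, among them MVK (-0.35 ± 0.33). Nuclear-encoded subunits of oxidative phosphorylation had a median of -0.06 (percentile 1.18), with 27 of 39 below 0, such as NDUFB5 (-0.36 ± 0.30). Genes of G1/S and DNA replication stood at -0.07 (percentile 1.45), with 23 of 34 below 0 and RRM2 at -0.32 ± 0.29. Autophagy and lysosome genes stood at -0.10 (percentile 1.70), with 17 of 23 below 0, although ULK1, an initiating kinase of autophagy, was at 0.50 ± 0.29. Fatty acid and lipid droplet genes stood at -0.12 (percentile 1.93) with 11 of 18 below 0, but their largest difference was that of fatty acid synthase, FASN, at 0.62 ± 0.31. None of these 5 lists had a member 1.5-fold lower. In a direct comparison of Cy5 after quantile normalisation, the medians of the oxidative phosphorylation, replication and autophagy lists changed sign to 0.06, 0.01 and 0.03. The autophagy and fatty acid lists also fell inside the range after the background correction with an added offset, at percentiles 19.0 and 8.54.

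The lists given next, some of them close to DOCK10's known biochemistry, lay inside the range, and 1 ranked list is not reported here. Other DOCK and ELMO genes had a median of 0.03 (percentile 72.9, 12 measured), with DOCK6 at 0.47 ± 0.31, DOCK9 at -0.40 ± 0.48 and DOCK3 at 0.35 ± 0.39. Effectors of Cdc42 and Rac stood at 0.02 (percentile 80.7, 43 measured), with 1 member beyond 2-fold, IQGAP2 (-1.03 ± 0.35). Its 1 probe lay in a deviating area of a slide, and IQGAP2 stood at -0.43 after the background correction with an added offset. Cytoskeletal targets of SRF and MRTF stood at 0.04 (percentile 87.2), and 2 of 24 passed 1.5-fold, FLNC (0.87 ± 0.41, but 0.22 after the background correction with an added offset) and MYH9 (0.75 ± 0.30). YAP and TAZ targets stood at 0.11 (percentile 95.9), with ARHGEF17 at 0.58 ± 0.32. Genes described in HEK293 as renal or embryonic stood at 0.07 (percentile 92.9) and interferon-stimulated genes at -0.10 (percentile 4.85), with IFIT2 (-0.76 ± 0.44) and IFIT1 (-0.60 ± 0.30) beyond 1.5-fold.

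**Figure D3:**
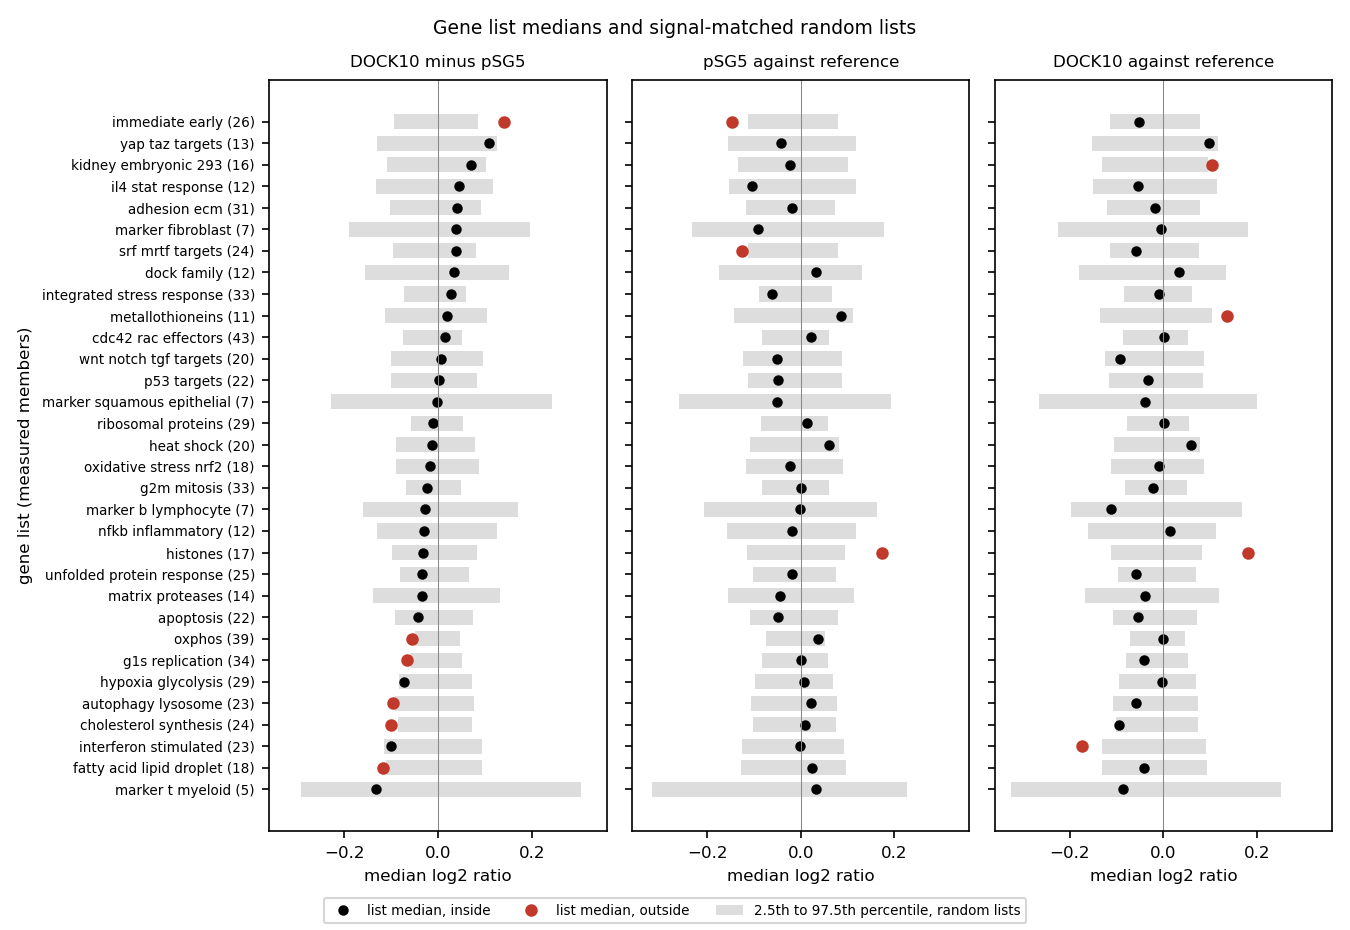
Median log2 value of each of 32 of the 33 ranked gene lists (points; measured members in brackets; 1 list is not shown) for DOCK10 minus pSG5 and for each array against the reference, with grey bars for the central 95% of 10000 signal-matched random lists. Immediate early genes lie above their bar in the left panel (0.14), and histone genes lie above theirs in both panels against the reference (0.17 and 0.18).

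For the next lists, the medians of DOCK10 minus pSG5 lay between the 4.68th and the 85.7th percentile. These were IL-4 and STAT response genes (0.04), adhesion and matrix genes (0.04), the integrated stress response (0.03), metallothioneins (0.02), Wnt, Notch and TGF-beta targets (0.01), p53 targets (0.00), ribosomal proteins (-0.01), heat shock genes (-0.01), NRF2 targets (-0.02), G2/M genes (-0.02), NF-kappaB genes (-0.03), histones (-0.03), the unfolded protein response (-0.04), matrix proteases (-0.04), apoptosis regulators (-0.04) and hypoxia and glycolysis genes (-0.07). Within G2/M, 2 of 33 genes passed 1.5-fold, the long mitotic transcripts CENPE (0.89 ± 0.29) and CENPF (0.77 ± 0.31). Markers of other cell types were mostly not measurable. B lymphocyte (-0.03), T lymphocyte and myeloid (-0.13), fibroblast (0.04) and squamous epithelial (0.00) markers had 5 to 7 measured genes each and medians inside the range, while erythroid and endothelial markers had 4 and 2 and were not ranked.

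Against untransfected cells, the empty vector array had 12 genes at least 2-fold higher and 14 lower, and the array labelled DOCK10 had 17 higher and 15 lower. These ratios have no dye swap and are open to dye bias. On both arrays 5 genes were higher and 3 lower, where independent lists would share 0.0160 and 0.0165. Both arrays used an untransfected reference and the same dye orientation, so the 2 lists are not independent of each other. NOTCH2NLA, a copy of the NOTCH2 amino terminus (1.42 on the pSG5 array and 1.80 on the array labelled DOCK10), SPATA13 (1.19 and 1.53), GPATCH1 (1.18 and 1.19), the synaptotagmin gene SYT1 (1.13 and 1.12) and CRCP (1.13 and 1.06) were higher. IBA57, of iron-sulfur cluster assembly (-1.45 and -1.10), WHR1, named STK19 by the authors (-1.14 and -1.18), and FXR2, a relative of the fragile X protein gene (-1.10 and -1.19), were lower. Errors of these single-array ratios were 0.24 to 0.29, and none of the 8 genes stayed beyond 2-fold on both arrays after the background correction with an added offset.

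Among the lists, histone genes, mostly replication-dependent ones, lay above the reference on both arrays, with medians of 0.17 (percentile 99.98) and 0.18 (percentile 99.99). Examples were H2BC4 (0.39 and 0.34) and H3C4 (0.34 and 0.23). On the pSG5 array, immediate early genes (-0.15, percentile 0.42) and cytoskeletal targets of SRF and MRTF (-0.13, percentile 1.35) lay below the reference, with filamin A, FLNA, at -1.32 on this array and -0.81 on the other. The immediate early members with the largest mean ratios nevertheless lay above the reference on the pSG5 array, JUND at 0.40, FOSB at 0.34 and JUN at 0.22. On the array labelled DOCK10, the same lists had medians of -0.05 and -0.06, inside the range. There, metallothioneins (0.14, percentile 99.3) and renal or embryonic genes (0.10, percentile 98.4) lay above the reference, and interferon-stimulated genes lay below it (-0.17, percentile 0.305). On the pSG5 array these lists lay inside the range, but metallothioneins stood at 0.09 (percentile 93.4), with 2 of 11 below the reference. The renal or embryonic members with the largest mean ratios were VIM (0.33 on the pSG5 array and 0.52 on the other), NEFL (0.33 and 0.33) and ENO2 (-0.53 and -0.68). Among interferon-stimulated genes, TRIM21 stood at -0.69 and -0.55, and USP18 at -0.28 and -0.45. These members thus deviated in the same direction on both arrays. After the background correction with an added offset, the SRF and MRTF (percentile 6.91), interferon (14.3) and renal or embryonic (77.3) lists fell inside the range, and the median of immediate early genes on the pSG5 array shrank to -0.08. Immediate early genes on the pSG5 array (percentile 0.46), histones and metallothioneins stayed outside the range.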

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

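All tests here were chosen after the results were seen, except that of the very long transcript list on the difference between the arrays, which was written before that list was computed. KIF24 and ND5 are listed because they lay at least 1.5-fold from the untransfected reference in opposite directions on the 2 arrays, a difference between the groups that was not tested. The difference was 1.39 for KIF24 (-0.71 on the pSG5 array and 0.68 on the array labelled DOCK10) and 1.58 for ND5 (-0.91 and 0.67). Probes without a gene name, which enter none of the comparisons, also differed: 33 of 3007 were at least 2-fold higher on the array labelled DOCK10 and 7 lower, while in the untransfected Cy3 channel alone 13 were higher and 218 lower. That is 1.10% of unnamed probes against 0.20% of named genes. The first share is over single probes and the second over genes averaged over their probes, so these shares are not directly comparable.

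For the first pattern, the 26 genes at least 2-fold higher on the array labelled DOCK10, slide differences in the reference channel would need a clearly lower Cy3 signal, and the median Cy3 difference was -0.0784. A lower yield of long transcripts in the pSG5 RNA would not by itself raise short transcripts, such as the mitochondrial ones. Their median difference was 0.84, or 0.64 without the 4 genes beyond 2-fold. Those genes were listed because ND5 and ND6 had been seen to be higher, so no other difference in yield or handling is excluded. Among the other higher genes, SCX and TNFRSF6B are short too, with gene lengths of 2029 and 2033 bases. For the long ones, a lower yield of long transcripts in the pSG5 RNA and a higher yield in the DOCK10 RNA cannot be told apart from an effect of the plasmid. Yield is confounded with the group, and the list of very long transcripts holds none of the 26. This list of 55 measured very long transcripts, such as HUWE1, had a median difference of 0.21 (percentile 100 of matched random lists), at percentile 54.2 against the reference on the pSG5 array and with a median of 0.17 at percentile 100 on the array labelled DOCK10. An effect of the DOCK10 plasmid and an unrecorded difference in handling the RNAs or slides stay open as well, untested.

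The second pattern is the 11 genes at least 2-fold lower. Their median Cy3 difference was 0.82, which is consistent with reference channel differences between the slides, or between reference extracts, as a source, and the share of them with a spot in a deviating slide area was 14.6 times that of all measured genes (54.5% against 3.73%). An effect of the plasmid on the lower genes stays open as well. C5AR2 and CPNE7, chosen here after their values were seen, had Cy5 differences of -0.98 and -1.34 with Cy3 differences of 0.08 and -0.32. Each was read by 1 dim probe (mean log2 signal 5.96 and 5.89). Their differences between the arrays shrank to -0.12 and -0.18 after the background correction with an added offset.

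The third pattern is the lack of DOCK10 signal on the array labelled DOCK10. Probes outside the transfected cDNA and low expression cannot be told apart, since 0 columns of the files give a probe sequence or position. A swap of the 2 arrays cannot be told apart from correct labels either, because 0 DOCK10 probes were well above background in Cy5 on the array labelled pSG5 and none on the other. No test of transfection itself was possible with these probes.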

How the results depend on the processing

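Leaving out slide areas, the reference channel criterion and leaving out very long transcripts were chosen after seeing the data; the other settings were not. No paired analysis was possible because each group held 1 array. With the authors' matrix and with median centring, all counts stayed within 1.5 times those reported. Both settings nearly repeat the main values and are little check. The matrix equalled the scanner ratios within 0.005, and the medians taken off were -0.0034 (pSG5) and -0.0108 (DOCK10). With normexp and loess, DOCK10 minus pSG5 gave 5 genes higher and 0 lower, pSG5 against the reference 0 and 0, DOCK10 against the reference 3 and 0, and both arrays 0; the added offset of 50 shrinks ratios by construction. Without a filter on dim probes (20348 genes), these were 514 and 605, 207 and 273, 320 and 499, and 77, and with the stricter filter (7505 genes) 12 and 1, 5 and 3, 14 and 1, and 5. That filter removes genes from the count, and all 5 of the 22 named genes still measured stayed beyond 2-fold. It leaves the values of the remaining probes as they were, so this is little check. The brightest probe gave 23 genes higher for pSG5 and 45 for DOCK10 against the reference, and 15 for both arrays; the cause was not tested. Direct Cy5 gave 67 higher and 120 lower after quantile normalisation and 62 and 123 after median centring. Shifts shared by both dyes of a spot do not cancel in that setting, and the cause of the larger counts was not tested. At 1.5-fold there were 233 and 116. Without deviating slide areas, 26 higher and 5 lower genes were left, with 9 lower for DOCK10 against the reference. Where the reference channel agreed within 1.5-fold, 24 higher and 3 lower were left. Lists outside the range numbered 4 to 8 for DOCK10 minus pSG5. For pSG5 against the reference they became 5 with background-subtracted signals, and the cause was not tested.

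Named genes mostly kept their direction. Of 22 genes named for the difference between the arrays, 22 kept it under normexp and loess, 4 of them beyond 2-fold. ITGA9 reversed to 0.0184 without a filter, and the cause was not tested. Of 13 settings, immediate early, cholesterol synthesis and oxidative phosphorylation genes stayed outside the range in 11 each, G1/S and replication genes in 9, autophagy and lysosome genes in 8 and fatty acid and lipid droplet genes in 7. Against the reference, of 10 settings, histones stayed outside in 9 (pSG5) and 10 (DOCK10), metallothioneins in 10, immediate early and renal or embryonic genes in 8 each, and interferon and SRF and MRTF genes in 7 each. The 13 and the 10 settings include the authors' matrix and median centring, which nearly repeat the main values. The autophagy list reached percentile 48.3 and the fatty acid list 31.75 at most; the cause was not tested. Under direct Cy5 with quantile normalisation, the medians of the replication, autophagy and oxidative phosphorylation lists reversed to 0.0106, 0.0294 and 0.0608, and with median centring that of autophagy to 0.0138; the cause was not tested. Signal over background limits what can be said of dim genes, which have bounds only.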

Other observations

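All lists and tests here were made after the main results were seen. Transcripts of the mitochondrial genome stood apart as a group. All 10 measured of its 13 protein-coding genes were higher on the array labelled DOCK10, with a median difference of 0.84 (percentile 100 of matched random lists), 7 of them by at least 1.5-fold and 4 by at least 2-fold. The list was made because ND5 and ND6 had been seen among the higher genes; without the 4 genes beyond 2-fold its median was 0.64 (percentile 100), and 0.54 with normexp and loess. ND5 (1.58 ± 0.39), ND6 (1.37 ± 0.41), CYTB (1.04 ± 0.30) and ATP6 (1.01 ± 0.30) differed most, and ND2 least (0.37 ± 0.30). Against the untransfected reference their median was -0.32 on the pSG5 array and 0.51 on the array labelled DOCK10. Nuclear-encoded subunits of the same complexes went slightly the other way, with a median of -0.06. That median changed sign to 0.06 when Cy5 was compared directly after quantile normalisation.

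Very long nuclear transcripts also shifted as a group, by less. Of 55 measured, 40 lay above 0, with a median difference of 0.21, and 4 passed 1.5-fold: SPEN (0.90 ± 0.30), PLEC (0.85 ± 0.32), RNF213 (0.84 ± 0.31) and KMT2A (0.63 ± 0.34). BIRC6 (-0.75 ± 0.40) went the other way, with a Cy3 difference of 0.83. Against the reference the median of the list was -0.01 on the pSG5 array and 0.17 on the array labelled DOCK10.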
